A study of Mus musculus with 4 samples.

How the data were processed

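RNA came from CH12.F3 cells, a mouse B lymphoma line, grown with 6% fetal calf serum and activated for 24 hours with CD40 ligand, TGF-beta and IL-4. Per the labels' protocols, total RNA was extracted with Trizol, purified on columns and labelled with the Affymetrix whole-transcript protocol. There are 4 arrays, 2 of control cells and 2 of Mbd4 KO cells, grouped by their titles. The deposited values are on a log2 scale, 1 per transcript cluster and array, and were made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalizes probe values by quantiles and summarises the probes of a cluster. Its version, software and settings are not given in the sources used here. The log2 scale was read from the deposited values, whose lowest lay between 2.693 and 2.816 and whose highest lay between 14.66 and 14.7 on the 4 arrays. No raw intensity was used here, so signal over background could not be assessed for single clusters.

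The platform's gene table, which can be old, paired 21789 of the 35556 clusters with exactly 1 gene symbol (19938 genes), 1621 with several, and 12146 with none in the table used. Only clusters with 1 symbol were tested and named, since probes of the others are shared or unnamed here. Of them, 123 shared all 4 values with another cluster, and 2 of these passed. Chromosomes and gene order came from the RefSeq annotation of assembly GRCm38.p6, in which 91 clusters found no chromosome. The array's own build is not given in the sources used here, so no coordinates are printed.

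The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither an intensity trend nor a robust prior), two-sided, with Benjamini-Hochberg adjustment over all tested clusters and a threshold of 0.05. No filter and no further normalization were applied. SE values are limma's moderated standard errors, with 2 residual and 4.00 prior degrees of freedom, and their median was 0.0777. The median SD between arrays was 0.0585 in the control group and 0.061 in the Mbd4 KO group. The number of arrays limits the precision: an exact two-sided permutation test of 1 value can give no p below 0.333, from 3 splits. No array was a copy of another, with at most 39 of 35556 values identical between any pair. This count cannot tell arrays of the same RNA from arrays of separate cultures.

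Gene lists, 31 in all with 825 genes, of which 727 were measured, were fixed before the data were examined. They were tested with limma's camera on 1 value per gene, the cluster with the highest mean, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members were counted as passing over all genes and, in a separate adjustment, over the list alone. The genes named in the text were also set by a rule fixed before the data were examined. They are Mbd4, the 12 largest rises and 12 largest falls among passing clusters whose groups did not overlap, the 4 largest differences in each list that passed, the 2 largest differences and any passing member in each other list, Ung, Tdg and Igha, and the annotated neighbours of Mbd4. Some genes that the rule takes in are not reported here. Genes named outside this rule are said to be so. The chromosome comparison was added after the changed genes had been seen. It used 9945 well-measured genes, windows of 30 genes, and a change-point search with 1000 shuffles of gene order per chromosome.

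The procedure was tested on simulated data for this comparison, with 200 of 21789 clusters changed. At a log2 change of 0.5 limma recovered 20% and at a change of 1 it recovered 94%, with 5 unchanged clusters called and 0 of the wrong sign. Camera with the preset correlation called 3 of 3 lists shifted by 0.2 and 0 of the others, while with an estimated correlation it called 0 of those 3. Failure with an estimated correlation therefore cannot count against a list. The clusters were simulated as independent of each other. The simulation thus does not show how the preset correlation fares where genes of a list vary together. Alternatives fixed before the data were examined were the replicate number as a block, each array left out in turn, an intensity trend or a robust prior in eBayes, removal of the dimmest 30% of clusters, quantile and cyclic loess normalization, all clusters of the table, limma's treat beyond 1.2-fold, a minimum of 1.5-fold, an adjusted p of 0.1, and no moderation of the variance. For the lists they were an estimated correlation, fry, ranks, and the mean of a gene's clusters. Leaving out chromosome 16 and the first part of chromosome 8 was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.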

Results

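Gene expression was measured on 4 whole-transcript oligonucleotide arrays hybridised with RNA from CH12.F3 cells, a mouse B lymphoma line that can be switched from IgM to IgA in culture. All cells had been activated for 24 hours with CD40 ligand (25% by volume), TGF-beta (0.2 ng/ml) and IL-4 (5 ng/ml), the stimuli that induce switching to IgA in this line. The arrays form 2 groups of 2, control cells and cells without Mbd4 (Mbd4 KO). Mbd4 is a DNA glycosylase that binds methylated CpG sites and removes thymine or uracil mispaired with guanine. The design compares activated cells with and without it, and holds no arrays of unactivated cells. The medians over all 35556 values of an array were 6.944 and 6.978 (log2) in the control arrays and 6.965 and 6.971 in the Mbd4 KO arrays. Across transcript clusters, which are not independent replicates, Pearson's r was 0.9979 between the control arrays, 0.9977 between the Mbd4 KO arrays and 0.9956 to 0.9958 between arrays of different groups. The labels do not say whether the arrays of a group came from separate cultures or separate knockout clones. The p-values thus measure only the spread between these arrays, which may be technical. For single genes and lists alike, a difference can come from the loss of Mbd4 or from another difference between these cells.

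Mbd4 itself, on chromosome 6, fell from 8.76 ± 0.021 in control cells to 6.48 ± 0.015 in Mbd4 KO cells (log2, mean ± SD, n = 2 each). The difference was -2.28 ± 0.066 (log2, SE), 4.86-fold lower, with an adjusted p of 0.0002 by limma with Benjamini-Hochberg adjustment. The 4 arrays thus ranked as their labels say, although the sources used here do not give where the probes of its 1 transcript cluster lie relative to the deleted part. Of the genes next to Mbd4 in the RefSeq annotation of assembly GRCm38.p6, Efcab12, of the EF-hand domain family, rose by 0.72 ± 0.10 (log2, SE; limma adjusted p = 0.0413), a call that did not hold with quantile or cyclic loess normalization (adjusted p = 0.0517 for both) or with any 1 array left out (0.0904 to 0.198). Snora7a, a small nucleolar RNA gene, differed by 0.20 (adjusted p = 0.315) and Ift122, an intraflagellar transport gene, by -0.13 (adjusted p = 0.501), and neither passed limma's threshold.

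The largest fall in Mbd4 KO cells was in Zfp979, a zinc-finger gene of a family with near copies on chromosome 4, so that its probes may read related genes. It fell by 4.28 on the log2 scale (SE 0.088; limma adjusted p = 0.000109), 19.5-fold. Its values in the Mbd4 KO arrays, 3.51 and 3.62, lay under the lower quartiles of these arrays (5.645 and 5.636), so the size of the fold is uncertain. Removal of the dimmest 30% of clusters took Zfp979 out, so that alternative did not test it. App, the amyloid precursor protein gene, fell by 3.23 (SE 0.084; 9.39-fold), Klhl6, a gene needed for germinal centre B cells, by 2.82 (SE 0.16), with limma adjusted p of 0.0002 and 0.0018. Adgrl2, a latrophilin adhesion receptor gene, fell by 2.67 (SE 0.14; adjusted p = 0.00151). All 8 clusters of Adgrl2 were lower and 7 of them passed, with differences from -2.67 to -0.50. The other falls named by rule were those of Arhgap29 (-2.56), the inhibitory receptor gene Cd200r1 (-2.56), the insulin-like growth factor 2 receptor gene Igf2r (-2.19), Gnat3 (-2.11), the HMG-box gene Bbx (-1.97), Lpp (-1.88) and the lymphocyte GTPase gene Gimap3 (-1.80). App, Klhl6, Cd200r1, Bbx and Lpp, 5 of the 12 largest falls, lie on chromosome 16, where most well-measured genes were lower, as given further on. Lpp had 1 other cluster that passed (-0.66) and 1 that did not (0.08).

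The largest rise was in Gemin8, which encodes a component of the SMN complex that assembles spliceosomal ribonucleoproteins. Its clusters rose by 2.49 ± 0.073 and 2.30 ± 0.081 (log2, SE), the larger being 5.61-fold, both past limma's threshold (adjusted p = 0.0002 and 0.00026). Where the probes of these clusters lie is not given in the sources used here, so they may read shared or related sequence. Adh4, an alcohol dehydrogenase gene, rose by 1.96 ± 0.11, Cd96, an immunoglobulin superfamily receptor gene, by 1.61 ± 0.082, and Sult5a1, a sulfotransferase gene, by 1.51 ± 0.090 (limma adjusted p = 0.00178, 0.00123 and 0.0022). Next in size were the phosphodiesterase gene Pde1c (1.34), the calsyntenin gene Clstn3 (1.34), Septin10 (1.32), Igfals (1.28), the transporter genes Abcc2 (1.27) and Slc24a4 (1.27), the nesprin gene Syne4 (1.27) and the JNK3 kinase gene Mapk10 (1.12). The second cluster of Mapk10 differed by 0.12 (adjusted p = 0.583) and did not pass.

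**Figure D1:**
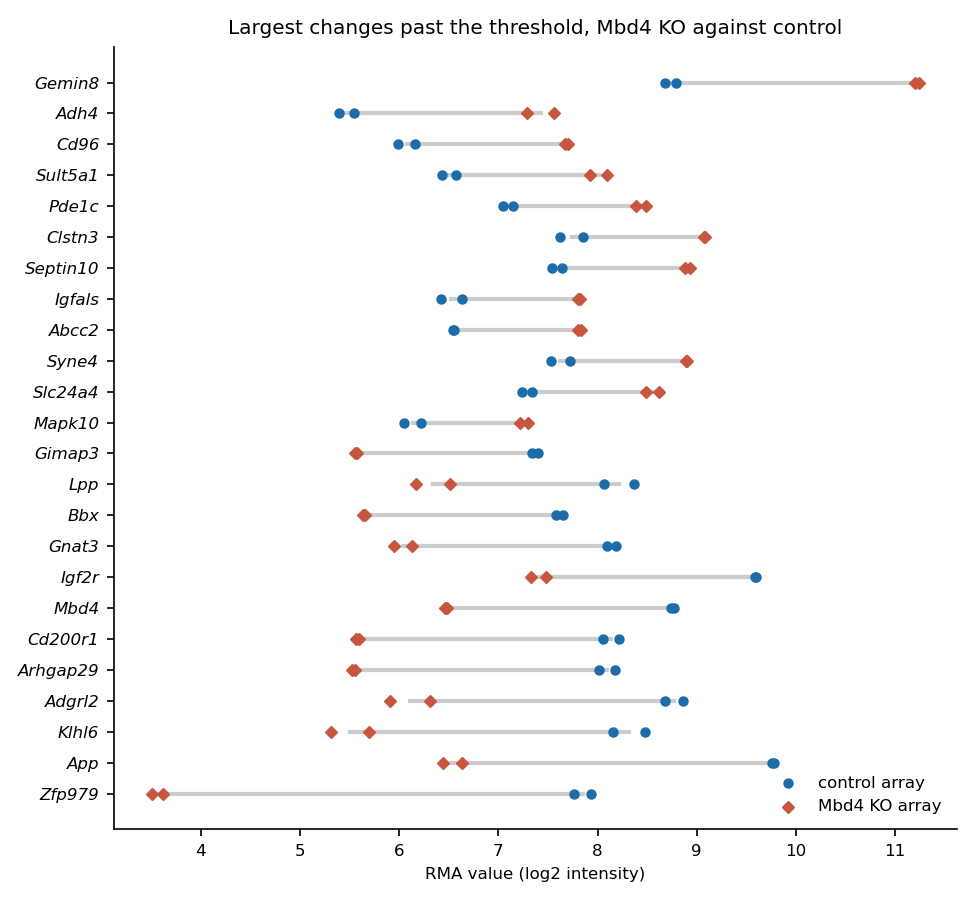
RMA values (log2 intensity, horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall past limma's threshold, 1 transcript cluster per gene. Circles are the 2 control arrays, diamonds the 2 Mbd4 KO arrays, and grey bars join the group means, which for Zfp979 lie at 7.85 and 3.57 and for Gemin8 at 8.74 and 11.2.

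Of 21789 transcript clusters tested, 302 passed limma's adjusted p threshold of 0.05, 94 higher and 208 lower in Mbd4 KO cells. They belong to 282 genes, 90 higher and 192 lower, and no gene had passing clusters in both directions. At least 2-fold changes were 16 higher and 46 lower, and the smallest fold among the passing clusters was 1.34. In all 302 the arrays of the groups did not overlap, as they did not in 44.97% of all clusters, where chance gives 33.3%. With any 1 array left out the count fell to between 65 and 75 (75 and 68 without control array 1 or 2, 67 and 65 without Mbd4 KO array 1 or 2), and 53 clusters passed in all 4 such fits. Of Mbd4 and the other largest changes, 23 of 24 passed in all 4, Mapk10 being the exception, whereas of the 21 other named genes that passed, only Bnip3, Il2ra and Adgre1 did.

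Genes of cholesterol biosynthesis were higher together in Mbd4 KO cells, by a median of 0.22 (log2) over the 20 members measured, 19 of which had values above zero. The largest differences were those of Fdps, farnesyl diphosphate synthase (0.45 ± 0.073, log2, SE; limma adjusted p = 0.0568), Msmo1 (0.37), Lss, lanosterol synthase (0.35), and Idi1 (0.35). None of the 20 passed over all genes, and 11 passed, all higher, when adjusted over the list alone. The list passed limma's camera test with a preset correlation (adjusted p = 3.23e-07 over 31 lists). It did not pass with the correlation of its genes estimated from these arrays (adjusted p = 0.581 with an estimated correlation). That setting also called 0 of 3 shifted lists in the simulated data. Failing it therefore counts neither for nor against this list or any list below, although it is given for them. The simulated clusters were independent of each other. How far the preset correlation overstates a list whose genes vary together is thus not known.

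Genes of glycolysis and the hypoxia response were also higher, with a median of 0.15 over 25 measured members, 21 of them above zero. Bnip3, a hypoxia-induced mitophagy receptor gene, rose by 1.06 ± 0.069 (log2, SE; limma adjusted p = 0.00307) and Vegfa, the vascular endothelial growth factor gene, by 0.54 ± 0.077 (adjusted p = 0.0415). The call of Vegfa was lost with quantile (adjusted p = 0.0611) or cyclic loess normalization (0.0524) and with any 1 array left out (0.124 to 0.213). The lactate transporter gene Slc16a3 (0.44) and the pyruvate dehydrogenase kinase gene Pdk1 (0.37) did not pass. The rises of Bnip3 and Vegfa were the 2 calls over all genes, and 9 members were higher when adjusted over the list alone. Camera gave an adjusted p of 6.42e-05, and an adjusted p = 0.581 with an estimated correlation. The cholesterol and glycolysis lists were the only 2 of 31 that passed with the preset correlation, and 0 passed with an estimated one.

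Several cytokine receptor genes and a chemokine gene were called lower in Mbd4 KO cells. Il2rb, the IL-2 receptor beta chain gene, fell by 1.05 (log2; SE 0.12), Il2ra, the alpha chain gene, by 0.95 (SE 0.069), Il7r by 0.67, Il15ra by 0.66 and Ccl22, a chemokine gene induced by IL-4 and CD40, by 0.66 (limma adjusted p = 0.021, 0.0044, 0.0132, 0.0145 and 0.0413). Il6ra rose by 0.60 (adjusted p = 0.0203). Among these genes only Il2ra kept its call whichever array was left out. Thus 1 of 38 measured members rose and 5 fell over all genes, against 1 higher and 7 lower adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.0522; adjusted p = 0.915 with an estimated correlation). It did pass, as lower, with an intensity trend in the prior (adjusted p = 0.0198), without the dimmest 30% of clusters (0.0259), without Mbd4 KO array 2 (0.0272). It also passed without the genes of chromosome 16 and the first part of chromosome 8 (0.0448). Ccl22 was also the 1 member of 29 that passed in the list of CD40 and NF-kappaB targets (camera adjusted p = 0.262; 0 higher and 3 lower adjusted over the list alone). In the list of IL-4 and STAT6 targets, 2 of 23 measured passed, Ccl22 and the cadherin gene Cdh17 (-0.58, adjusted p = 0.0333). Camera gave that list an adjusted p of 0.58, with 1 higher and 3 lower adjusted over the list alone. Among the 3 is Fcer2a (-0.37), named outside the rule. It lies in the first part of chromosome 8, where the median of well-measured genes was -0.30. Among 28 targets of TGF-beta and SMAD, Id3, an inhibitor of E-protein transcription factors, fell by 0.78 (adjusted p = 0.00903), and Smad3 differed by 0.42 (adjusted p = 0.065; camera adjusted p = 0.392; 2 higher and 1 lower adjusted over the list alone). Cdh17 and Id3 lost their calls with any 1 array left out.

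**Figure D2:**
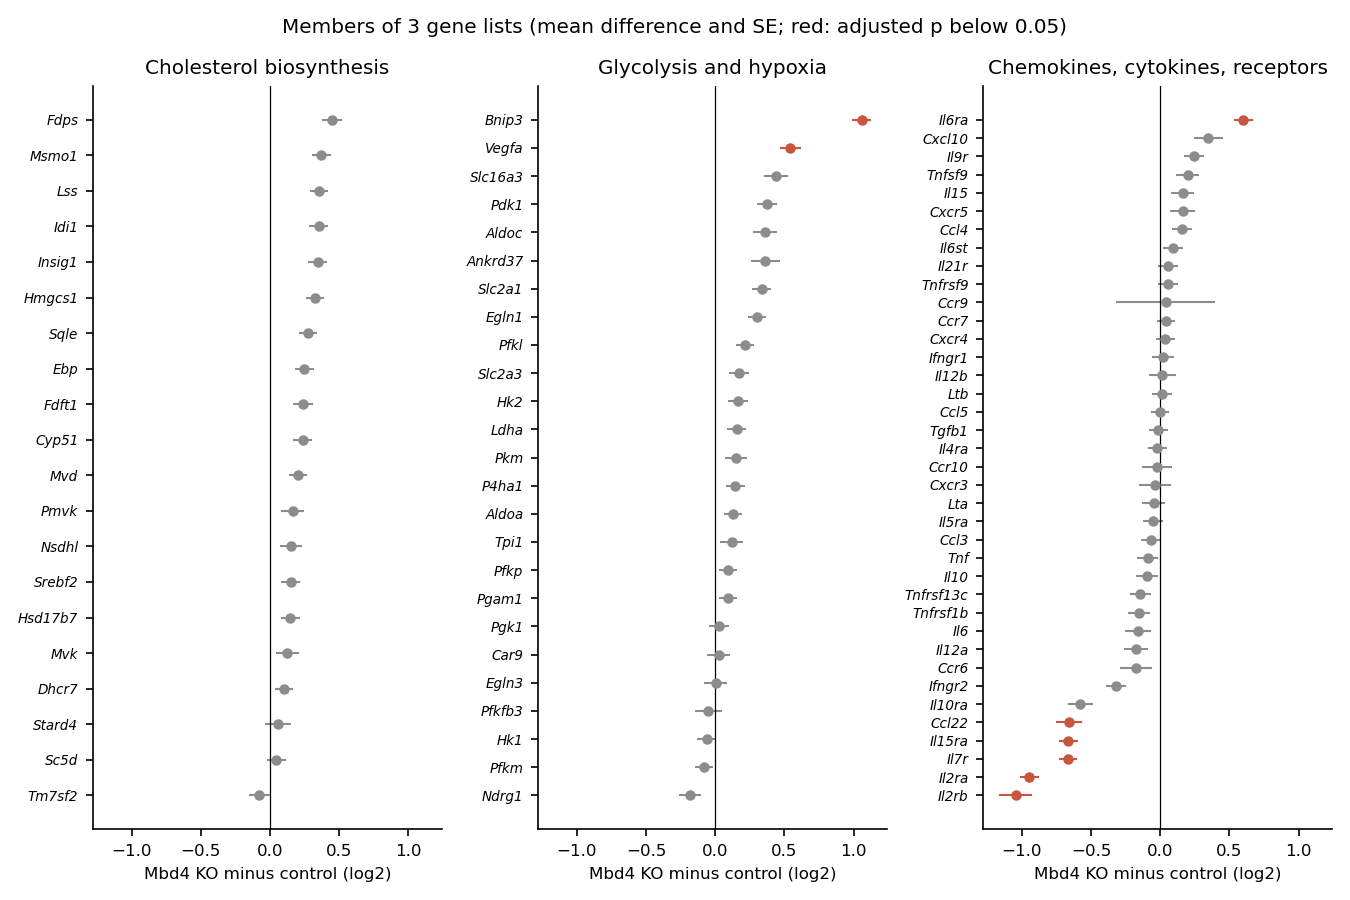
Difference between Mbd4 KO and control cells (log2, mean with SE as bars, 2 arrays per group, horizontal axis) for each measured member of the cholesterol biosynthesis list, the glycolysis and hypoxia list and the list of chemokines, cytokines and receptors. Red points passed limma over all genes: 0 of 20, 2 of 25 and 6 of 38, the last with 5 below zero.

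B cell identity genes included Cd72, a B cell co-receptor gene, which fell by 0.67 (SE 0.072; limma adjusted p = 0.0155), and Bach2, a repressor of plasma cell differentiation, which fell by 0.49 (adjusted p = 0.0492). Cd72 lost its call with any 1 array left out. The call of Bach2, here and among the germinal centre genes, was lost with the robust prior (adjusted p = 0.0521), with quantile normalization (0.0521), without the genes of chromosome 16 and the first part of chromosome 8 (0.0578) and with any 1 array left out (0.157 to 0.241). No other of the 25 measured passed over all genes, 3 were higher and 4 lower adjusted over the list alone, and camera gave an adjusted p of 0.0512. The list passed, as lower, with an intensity trend (adjusted p = 0.00433), without the dimmest 30% of clusters (0.028), without control array 1 (0.0424) or Mbd4 KO array 2 (0.0272) and without those chromosome 16 and 8 genes (0.0438). It did not pass with an estimated correlation (adjusted p = 0.915). Of 21 plasma cell genes, 1 passed: Jchain, which encodes the joining chain of IgA and IgM polymers, rose by 0.43 (adjusted p = 0.045; camera adjusted p = 0.392; 1 higher adjusted over the list alone). The call of Jchain, here and among the immunoglobulin genes, was lost without those chromosome 16 and 8 genes (adjusted p = 0.0526) and with any 1 array left out (0.21 to 0.228). Bach2 was the only germinal centre gene of 20 to pass, and the death receptor gene Fas differed by -0.51 (adjusted p = 0.0744). Camera gave this list an adjusted p of 0.319, with 3 higher and 6 lower adjusted over the list alone. Of these, Cd86 (-0.27) and Bcl6 (0.27), both named outside the rule, lie on chromosome 16. Among 9 immunoglobulin genes measured, Jchain rose and Vpreb3, of the surrogate light chain family, fell by 0.79 (adjusted p = 0.0101; camera adjusted p = 0.744; 2 higher and 1 lower adjusted over the list alone). Vpreb3 also lost its call with any 1 array left out. The Igha constant region gene, the product of switching in these cells, differed by 0.21 (adjusted p = 0.451) in 1 cluster and by -0.00081 (adjusted p = 0.999) in the other, and limma called neither. Both clusters were dim, with means of 6.32 and 6.09 (log2) in control cells and 6.53 and 6.09 in Mbd4 KO cells. These lie under 7.152, the cut used further on for well-measured genes, so a change in Igha could go unseen.

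Genes of class switch recombination and its cofactors showed no call over all genes among 39 measured, and 0 adjusted over the list alone (camera adjusted p = 0.907). Limma's fry, run for changes in either direction, gave this list an adjusted p of 0.00323. By that test 24 of 31 lists passed, so it does not set this list apart. Base excision repair (0.00133, with Mbd4 a member) and non-homologous end joining (0.00418) were among them. Atm, the double-strand break kinase gene, differed by 0.35 (limma adjusted p = 0.0869) and the ubiquitin ligase gene Rnf168 by -0.30 (adjusted p = 0.157). With an intensity trend in the prior, limma called Atm (adjusted p = 0.00638) and Rnf168 (0.0121). It also called Prkdc (0.0375), Brca2 (0.0299) and Slx4 (0.0452), but not Lig4, Pold4 or Msh3. Without the dimmest 30% of clusters only Atm of these was called (0.0337). In the simulated data limma without a trend recovered 20% of log2 changes of 0.5, so changes of this size can go unseen. Ung, the uracil DNA glycosylase gene, differed by 0.10 ± 0.068 (log2, SE; adjusted p = 0.59). Tdg was not analysed here. In base excision repair, Mbd4 and Polb, the DNA polymerase beta gene, were the 2 of 24 that passed, Polb falling by 0.50 (adjusted p = 0.0449; camera adjusted p = 0.891; 2 lower adjusted over the list alone). Polb was not called with any 1 array left out or with the replicate number as a block (limma adjusted p = 0.071). Polb and Lig4 lie in the first part of chromosome 8, and Rnf168, Prkdc and Slx4 on chromosome 16, regions whose well-measured genes had medians of -0.30 and -0.28. Mismatch repair (20 measured, Pold4 -0.24 and Msh3 0.20), non-homologous end joining (15 measured, Prkdc -0.26 and Lig4 -0.21) and homologous recombination with the Fanconi anaemia pathway (26 measured, Slx4 -0.30 and Brca2 0.27) had 0 passing members by either adjustment, with camera adjusted p of 0.907, 0.911 and 0.814. Among 24 readers, writers and erasers of DNA methylation, Tet1, a 5-methylcytosine dioxygenase gene, rose by 0.52 (adjusted p = 0.0413) and Mbd4 fell (camera adjusted p = 0.891; 2 higher and 1 lower adjusted over the list alone). Leaving out any 1 array ended the call of Tet1, as did the replicate number as a block (limma adjusted p = 0.0763). Germline genes that promoter methylation silences had 0 of 24 passing by either adjustment (Tuba3b 0.54, Hormad1 -0.29; camera adjusted p = 0.898).

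Of 26 p53 targets, Plk2, a polo-like kinase gene, fell by 0.61 (limma adjusted p = 0.0354; camera adjusted p = 0.761; 1 higher and 2 lower adjusted over the list alone). Plk2 lost its call with any 1 array left out and with the replicate number as a block (limma adjusted p = 0.0748). Of 39 S phase genes, Chaf1b, a chromatin assembly factor gene on chromosome 16, fell by 0.44 (adjusted p = 0.0476), Pole2 differed by -0.35, and camera gave an adjusted p of 0.0587, with 4 lower adjusted over the list alone. The S phase list passed with an intensity trend (0.0198) and without control array 1 (0.0156) or Mbd4 KO array 2 (0.0321), but not with an estimated correlation (adjusted p = 0.915). It did not pass without the genes of chromosome 16 and the first part of chromosome 8 either (adjusted p = 0.339). The call of Chaf1b was lost with quantile normalization (adjusted p = 0.0574) and with any 1 array left out (0.189 to 0.247). No member passed over all genes in the lists of G2 and M phase (Nuf2 -0.20, Espl1 0.19), apoptosis (Bbc3 0.27), the unfolded protein response (Trib3 0.44, Dnajb11 -0.43), interferon response (Ddx58 -0.38, Cxcl10 0.35), replication-dependent histones (H2bc3 -0.17, H1f3 0.16), MYC and ribosome biogenesis (Myc 0.24, Polr1a 0.20), cytosolic ribosomal proteins (Rpl24 -0.28, Rpl12 0.16) and oxidative phosphorylation (Atp5o -0.32, Ndufv1 0.18). Their camera adjusted p were 0.58, 0.907, 0.898, 0.0929, 0.891, 0.0929, 0.907 and 0.907. Adjusted over the list alone, 1 member was lower in the apoptosis list and 1 in the interferon list. There were 3 higher and 2 lower in the unfolded protein response. Dnajb11, Rpl24 and Atp5o lie on chromosome 16. The interferon list passed, as lower, without the dimmest 30% of clusters (camera adjusted p = 0.0259) and without control array 1 (0.0421) or Mbd4 KO array 2 (0.0459), but not with an estimated correlation (adjusted p = 0.915). The MYC list passed, as higher, with an intensity trend (0.00433), quantile (0.0397) or cyclic loess normalization (0.0328), but not with an estimated correlation (adjusted p = 0.915).

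No list of markers of other cell types passed camera in the fit of all clusters. The macrophage and granulocyte list passed, as lower, without the dimmest 30% of clusters (adjusted p = 0.0259), its mean going from -0.08 to -0.15 (log2). It did not pass with an estimated correlation (adjusted p = 0.915) or on ranks (0.437). Adgre1, the macrophage marker F4/80, fell by 1.06 (SE 0.070; limma adjusted p = 0.00311) as the only 1 of 25 macrophage and granulocyte markers to pass, by either adjustment (camera adjusted p = 0.117). Vim, the vimentin gene, fell by 0.83 (adjusted p = 0.00775), the 1 of 18 fibroblast and epithelial markers to pass, with Pdgfrb at -0.52 (camera adjusted p = 0.58; 2 lower adjusted over the list alone). Vim lost its call with any 1 array left out. T and NK cell markers (19 measured, Cd3g 0.42 and Prf1 -0.37) and progenitor and erythroid markers (14 measured, Alas2 0.19 and Kit -0.18) had 0 passing members over all genes, with camera adjusted p of 0.814 and 0.778, and 1 T and NK marker was lower adjusted over the list alone. In 12 lists the median, the mean and camera's direction did not all share a sign: base excision repair, mismatch repair, non-homologous end joining, DNA methylation, germline genes, G2 and M phase, apoptosis, the unfolded protein response, oxidative phosphorylation, and the macrophage, fibroblast, and T and NK markers.

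The place of the changed genes along the chromosomes was examined only after those genes had been seen, with gene order from the RefSeq annotation of assembly GRCm38.p6. On chromosome 16, 41 of 703 clusters passed limma, 40 of them lower and Cd96 the 1 higher, which is 5.83% against 1.18% outside this chromosome and the first part of chromosome 8. Over the 316 well-measured genes of chromosome 16, those with a mean above the median of 7.152, the median difference was -0.28 (log2), and 92.1% had values below zero. The median over its 332 dimmer genes was 0.0078. The 2 Mbd4 KO arrays gave medians of -0.30 and -0.25 against the control mean, while the control arrays differed from each other by 0.022. The first part of chromosome 8, through Dusp4 and ending before Tnks, gave a median of -0.30 over 100 well-measured genes against 0.03 over the rest of the chromosome, and 17 of its 231 clusters passed, all lower. The change point after Dusp4 had a shuffled p of 0.001, the smallest that 1000 shuffles can give, and an adjusted p of 0.02 over 20 chromosomes. A change point near the end of chromosome 4 also had an adjusted p of 0.02, with medians of 0.01 before and 0.10 after it, and on chromosome 12 the median was -0.06 with 68.4% of genes below zero. Without the genes of chromosome 16 and of the first part of chromosome 8, 185 clusters passed, 65 higher and 120 lower.

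**Figure D3:**
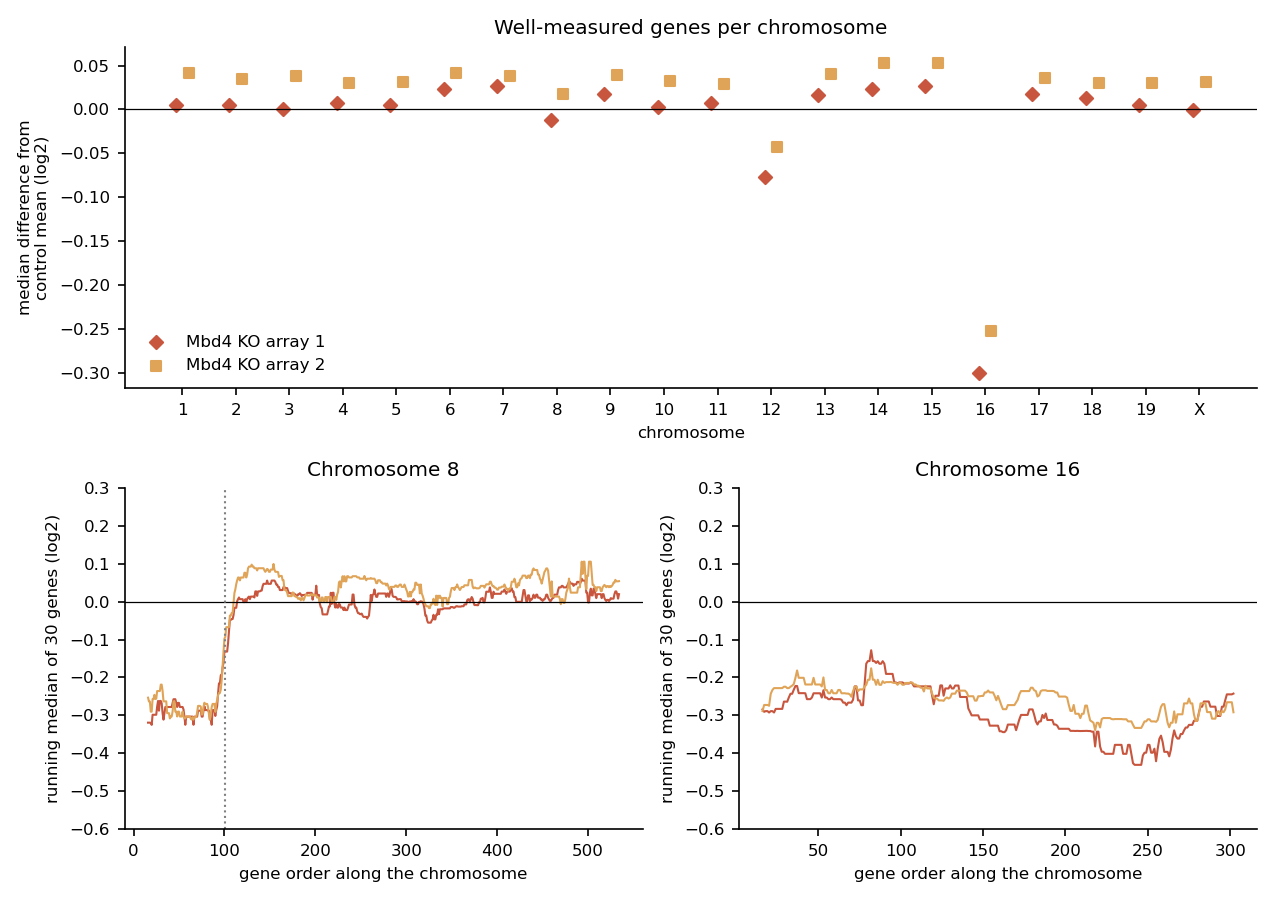
The upper panel gives, for each chromosome, the median difference of each Mbd4 KO array from the control mean (log2) over well-measured genes. The lower panels give the running median of 30 genes in gene order along chromosomes 8 and 16 for the same 2 arrays, with a dotted line after Dusp4, where the median passes from -0.30 to 0.03. Chromosome 16 lies at -0.30 and -0.25 in the 2 arrays.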

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

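The fit without chromosome 16 and the first part of chromosome 8 was chosen after the results were seen, and the others given here before. The fall of Mbd4, which was not run for the other thresholds (1.2-fold, 1.5-fold, adjusted p of 0.1), held its call in every other fit except the one without moderation of the variance (-2.28, limma adjusted p = 0.153; range over its alternatives 4.62e-08 to 0.153), and it lay between -2.30 and -2.27 with 1 array left out. The count of 302 clusters (94 higher, 208 lower) was 65 to 75 with 1 array left out (17 to 22 higher, 46 to 54 lower), the lone array being assumed to vary like the other group. It was 1121 (398 and 723) with an intensity trend, 640 (224 and 416) without the dimmest 30%, 22 (5 and 17) over all clusters of the table, 88 (23 and 65) for a change beyond 1.2-fold, 185 (56 and 129) with at least 1.5-fold, 593 (209 and 384) at an adjusted p of 0.1, and 0 (0 and 0) with no moderation, where 2469 had an unadjusted p under 0.05. Without the genes of chromosome 16 and the first part of chromosome 8 it was 185 (65 and 120). Only 58 of the 302 lay in these regions, so calls of genes elsewhere were lost too. Apart from the stricter thresholds, the cause of these differences in count was not tested. Robust, quantile and cyclic loess fits gave 291, 252 and 293. The array numbers share only a number: deviations of same-numbered arrays correlated at 0.0831, no label ties them to a shared day, and with the replicate number as a block 159 passed (45 and 114), 152 of them among the 302, and 10 other named genes were not called. The 2 passing lists became 0 with an estimated correlation, 1 with fry, 6 with an intensity trend, 6 without the dimmest clusters, 4 without the chromosome 16 and 8 genes, and 2 to 6 with 1 array left out (5 without control array 1, 6 without Mbd4 KO array 2). Lists that gained a call were, as lower, B cell identity and the cytokine list with an intensity trend, without the dimmest clusters, without Mbd4 KO array 2 and without the chromosome 16 and 8 genes (B cell identity also without control array 1). Others that gained one, as lower, were S phase with the trend and without either of those arrays, interferon response without the dimmest clusters or either array, and macrophage markers without the dimmest clusters. The MYC list gained one, as higher, with the trend, quantile or cyclic loess normalization. The cholesterol list (mean 0.21, camera) and the glycolysis list (mean 0.20) lost their calls with an estimated correlation (0.212 and 0.196, adjusted p = 0.581), and the glycolysis list also with fry (0.196, adjusted p = 0.0555). H2bc3, not called, ranged from -0.463 to 0.129 with 1 array left out and was above zero without Mbd4 KO array 2. The second Igha cluster, not called, ranged from -0.15 to 0.15, at 0.10 without control array 1 and 0.15 without Mbd4 KO array 2. Of the 90 other named results, 18 lost their call in each fit with 1 array left out, 4 with quantile normalization (Bach2, Chaf1b, Vegfa and Efcab12), 2 with cyclic loess (Vegfa and Efcab12), 1 with the robust prior (Bach2) and 2 without the chromosome 16 and 8 genes (Bach2 and Jchain). Calls were lost by 32 over all clusters and by 44 with no moderation, while 25 gained one with an intensity trend and 15 without the dimmest clusters. Signal over background was not used here, so how far dim clusters limit these fits is unknown.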

Other observations

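The tests of DNA copy number, of a direct effect of Mbd4 loss and of the Mbd4 locus were chosen only after the results were seen, as were the genes named in the next paragraph and the alternative without the genes of chromosome 16 and the first part of chromosome 8 and the Fisher tests with 1 array left out.

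Outside the rule for named genes, these genes passed limma's threshold and were picked after their values were seen, so they stand for no theme. The fatty acid binding protein gene Fabp5 fell in both passing clusters (-1.69 and -1.58), Gimap4 fell by 1.30 beside Gimap3, and 4 clusters of Nlrc5, a transactivator of MHC class I genes, fell by 0.51 to 0.73. The transcription factor gene Stat4 fell by 1.05. Cd200r4 (-0.90) and Cd200r2 (-0.88), near copies of Cd200r1 on chromosome 16, also fell. Tnfrsf18, which encodes the receptor GITR, rose by 1.07.

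In the list of chemokines, cytokines and receptors, 6 of 38 genes passed (15.8%) against 273 of the 19937 genes other than Mbd4 (1.37%), counting for each gene only the cluster with the highest mean. A one-sided Fisher's exact test gave an adjusted p of 0.00037 over the 31 lists, but it restates that count and genes of a list are not independent. With 1 array left out, 1 or 2 members passed and the adjusted p was 0.153 to 1, so whether the list is enriched stays open. The S phase list had an unadjusted camera p of 0.00946 with its 39 members and 0.0985 with the 34 that lie outside chromosome 16 and the first part of chromosome 8. The 4 arrays allow 3 splits into groups of 2, too few for a share under 0.05, and 1 of them, the real one, gave 302 passing clusters while the highest other gave 0.

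Values of well-measured genes along chromosome 16 and the first part of chromosome 8 were lower in both Mbd4 KO arrays. An intensity-dependent effect of the normalization is argued against by 10000 gene sets from other chromosomes matched on mean intensity, whose lowest median was -0.0101 (log2) against -0.28 on chromosome 16. On chromosome 16, 10 of 10 windows of 30 genes lay below the 1st percentile of windows elsewhere, between -0.34 and -0.23, which describes the shift again and does not test its cause. The 2 Mbd4 KO arrays shared the shift, differing by only 0.047 in the chromosome 16 median. Either a lower DNA copy number or a direct effect of Mbd4 loss could give this. The labels do not say whether the arrays come from separate clones. The shift followed position, with no window elsewhere below -0.131. On chromosome 8 it ended after Dusp4, with medians of -0.30 before and 0.03 after. For the well-measured genes of these regions, this argues against a direct effect on single genes wherever they lie. No DNA measurement was used here, so a lower copy number and an effect of Mbd4 loss on whole regions stay open.

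More clusters fell (208) than rose (94). The genes of chromosome 16 and the first part of chromosome 8 are not the whole of it, since without them 35.1% of the passing clusters were higher, against 31.1% with them. The share was at most 29% under quantile or cyclic loess normalization, but these move values that RMA had already normalized very little, so the scaling of the arrays stays open. A biological excess of falls after loss of Mbd4 stays open and was not tested.

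Efcab12, next to Mbd4, rose in Mbd4 KO cells by 0.72 (log2). Of 10000 random sets of 3 clusters, the number of neighbours measured, 1.78% held a change as large, but this restates the size of a change picked because it had passed and does not bear on an effect of the targeting at this locus, which stays open. The limma call is fragile, with adjusted p from 0.00298 to 0.4 over the alternatives, and the 2 other measured neighbours, Snora7a and Ift122, were not called. How the knockout was made is not given in the sources used here.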
